A study of Solanum lycopersicum with 12 samples.

How the data were processed

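Gene expression was measured on Affymetrix tomato arrays in 12 samples of wild-type Micro-Tom, 3 for each of 4 groups: seeds at day 1 and seedlings at day 11, each on medium with or without 25 ug/ml carbon nanohorns (SWCNH). RNA was extracted with a plant mini kit and labelled with a 3' IVT kit, per the labels' protocols. The deposited values are linear signal intensities, which the authors made with GCOS, per the submitters' processing notes, with no version named. On every array the trimmed mean, with 2% left out at each end, was 500, so the deposited intensities had been scaled to a common target. No detection calls were used. The table held 10209 probe sets, of which 108 Affymetrix controls were left out of the tests and 10101 were tested.

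Gene symbols came from the platform annotation and a RefSeq table. Of the tested probe sets 909 carried 1 symbol, 0 carried several and 9192 carried none, and 786 of 803 genes were matched in the RefSeq table. For 176 genes the only symbol was an LOC number, and counts of genes in lists cover the named genes only. Of 25 gene lists fixed beforehand, 24 had a gene on the array, 17 had at least 5 and were tested, and 272 genes were in any list. The seed storage protein list matched no gene. The lists had been fixed with patterns for gene descriptions, which could not be used with this annotation. Members were instead assigned by symbol and synonym, after the files were seen and before group differences were computed, so list membership is not wholly that fixed beforehand.

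Signals were transformed as log2 of the value plus 16 and fitted in limma 3.58.1 under R 4.3.3, with a mean for each group over all 12 arrays, 8 residual degrees of freedom and empirical Bayes moderation with a trend. P-values were adjusted by the Benjamini-Hochberg method over 10101 probe sets, and probe sets with an adjusted p under 0.05 are said to have risen, fallen or passed. Adjusted p-values in the text are limma's, and SE is its moderated standard error. Log2 fold changes and fold minimums are on this transformed scale, where the added 16 makes changes of low signals smaller than the ratio of mean signals. The comparisons were SWCNH minus control in seeds and in seedlings, the difference between these responses, and seedlings minus seeds on control medium. Lists were tested with camera at a preset correlation of 0.01 between genes, against the other named genes, with the probe set of highest mean for each gene. They were also tested with an estimated correlation and with fry, which asks whether genes of a list move on balance one way and does not compare them with other genes.

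Named genes were chosen by a rule. For each SWCNH comparison it took the 12 largest rises and the 12 largest falls among genes that passed with no overlap between groups, filled to 5 per direction by smallest p where fewer passed. For the stage comparison it took 10 per direction, for the difference in response the 5 of smallest p per direction, and for each list the 2 members of smallest p in each SWCNH comparison. A signal is called below the level of probe sets without a target where it is under the 95th percentile of 23 such controls. Between 79.3% and 92.7% of probe sets lay above that level on an array, and median signals were 104 to 186. The median SD between replicates was 0.213 log2 units in seeds and 0.146 in seedlings. RNA integrity was read from the 5'/3' ratios of tomato control transcripts.

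The test was run on simulated data for 10101 probe sets, with 50 changed at each fold. The changed ones were drawn only from probe sets above the median of mean signal, and folds were added on the transformed scale. Noise was independent between probe sets, unlike variation that real arrays share. The shares recovered therefore do not cover probe sets of low signal. For seeds, 82%, 96%, 98% and 100% of changes of 1.5, 2, 3 and 4-fold were recovered, and 67 of 255 calls were false. With only the 6 seed arrays, 42%, 66%, 90% and 94% were recovered and 7 of 153 calls were false. For seedlings the shares were 58%, 94%, 100% and 98% with 7 of 182 false, and with only the 6 seedling arrays 78%, 98%, 100% and 100% with 3 of 191 false. For the difference in response they were 24%, 74%, 88% and 96%, with 16 of 157 false. An auxin list shifted by 0.5 log2 units in simulated seedlings was found by camera (adjusted p = 1.2e-20), with 0 other lists called.

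Alternatives covered the threshold, pseudocount, normalization, filters on low signals, variance model, array weights, arrays fitted together and each array left out in turn. Chosen after seeing the data were a 5'/3' covariate, scaling to the poly-A spike-ins added before labelling, leaving out the pair of seed arrays with the lowest 5'/3' ratio, and all probe sets as the background for lists. Among 66 pairs of arrays 0 were identical.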

Results

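Tomato plants of the dwarf cultivar Micro-Tom, wild type, were germinated on MS agar, a standard plant culture medium, with or without carbon nanohorns, which are horn-shaped carbon nanoparticles abbreviated SWCNH in the sample labels. The SWCNH medium held 25 ug/ml, and total RNA was taken from seeds after 1 day and from seedlings after 11 days. Each of the 4 groups (control seeds, SWCNH seeds, control seedlings, SWCNH seedlings) had 3 arrays, 12 in all, on the Affymetrix tomato array. The series title names multi-wall nanohorns, roots and leaves, whereas the sample labels name SWCNH, seeds and seedlings, and the sample labels were followed here. Values were signal intensities of 10101 tomato probe sets, of which 909 carried a gene symbol, for 803 genes. Replicates of a group correlated with r between 0.980 and 0.995 on the log2 scale across probe sets, which are not independent replicates. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value. The topics and symbols of the gene lists, the tests of the comparisons and the rule for named genes were fixed before the data were examined. Genes were matched to lists after the files were seen, before group differences were computed, and other additions are said to be later.

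The first comparison asked how seeds differed after 1 day on SWCNH medium. No probe set passed limma's test, and the named genes with the smallest p are given as values only. EXP2, an expansin that loosens cell walls, had the smallest p of the named genes, with a mean signal of 2737 ± 195 (SD, n = 3) in SWCNH seeds and 1917 ± 79.2 in control seeds. Its log2 fold change was 0.51 (SE 0.08), with a limma Benjamini-Hochberg adjusted p of 0.237. MT4, a metallothionein that binds metals, had a log2 difference of 1.02 (SE 0.24, adjusted p = 0.338), with 3569 ± 264 in SWCNH seeds against 1921 ± 1060 in control seeds. Its 3 other probe sets had log2 differences of the same sign, from 0.09 to 0.60. LEJA1 had a log2 difference of 0.56 (SE 0.13), at 137 ± 19.5 against 87.3 ± 9.03. For KD1 (0.54) and the iron superoxide dismutase FESOD (0.31), another probe set of the gene had the opposite sign (-0.17 and -0.38), and the control signal of KD1 lay below the level of probe sets without a target. Among values below 0, LOC543548 had -0.51 (SE 0.12), at 319 ± 37.0 in SWCNH seeds and 464 ± 71.8 in control seeds. The ethylene receptor gene ETR4 had -0.40 (SE 0.12), at 649 ± 77.9 against 860 ± 113. LOC543825, PsbQ and LOC543730 (-0.82, -0.43 and -0.53) had SWCNH signals below the level of the array's probe sets without a target, and LOC543730 was below it on both media.

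Among the gene lists in seeds, the 10 auxin genes had positive log2 fold changes at their probe set of highest mean, with a median of 0.18. IAA7 and IAA17 were below the level of probe sets without a target, and another probe set of IAA7 had the opposite sign. The members with the smallest p were IAA3, a repressor of auxin response (0.66, SE 0.20), and RSI-1 (0.38, SE 0.13). The list passed the camera set test as higher on SWCNH, with an adjusted p of 0.00160 over 17 lists. That call was lost with the correlation between genes estimated from the data (adjusted p = 0.192 with an estimated correlation) and by fry (adjusted p = 0.182). No single auxin gene passed, also when adjusted over the list alone. The 5 genes for weakening of the endosperm, the tissue around the embryo, passed as higher at an adjusted p of 0.0499 (adjusted p = 0.192 with an estimated correlation). Of these, the endo-beta-mannanase MAN2 had 0.52 (SE 0.17), EXPA4 0.23 (SE 0.09) and MAN1 -0.04 (SE 0.24). That call ended without control replicate 2 (adjusted p = 0.101), control replicate 3 (0.147), SWCNH replicate 1 (0.162) or SWCNH replicate 3 (0.0662). Without control replicate 1 the photosynthesis list passed as well, as lower on SWCNH (adjusted p = 0.0385). Seed signals of its genes were low, with group means from 0.865 (CAB5 on SWCNH) to 32.6 (CAB4 on control medium). CAB5 lay below the level of probe sets without a target on both media, and PsbQ on SWCNH. Adjusted over the list alone, 1 gene passed in each of 5 lists: LEJA1 higher among jasmonate and wound genes, EXP2 higher in cell wall remodelling, MAN2 higher in endosperm weakening, PsbQ lower in photosynthesis and gMDH, a glyoxysomal malate dehydrogenase, lower in reserve mobilisation. In every list, no gene passed in seeds when adjusted over all probe sets.

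In total, 0 of 10101 probe sets passed limma's test in seeds at an adjusted p under 0.05, while 834 had an unadjusted p under 0.05 and 505 would by chance. Without control replicate 3, 1 probe set passed, that of MT4 (log2 fold change 1.43, adjusted p = 4.74e-05), and with a pseudocount of 1 there were 11, of which 9 had mean seed signals under 16 and 1 was EXP2 (adjusted p = 0.0353). The 5'/3' log2 ratio of tomato control transcripts, a sign of RNA integrity, ranged from -3.17 to -1.51 over the seed arrays (mean -2.23 on SWCNH and -2.14 on control medium). In data simulated on these seeds, 67 of 255 calls were false (26.3%) with the spread shared by all groups.

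In seedlings after 11 days on SWCNH medium, 4 of 16 pathogenesis-related genes rose and 2 fell, and 3 of 9 phenylpropanoid and flavonoid genes fell and 1 rose. P69B, a subtilisin-like protease of the pathogenesis-related class, rose most among named genes, from 74.7 ± 20.3 in control to 464 ± 48.4 in SWCNH seedlings (SD, n = 3; log2 fold change 2.42, SE 0.19, adjusted p = 1.07e-05). TSI-1, a stress-induced protein of the PR-10 type, rose from 26.0 ± 8.60 to 104 ± 9.05 (1.54, SE 0.18), and PR1b1, a PR-1 protein, from 25.8 ± 4.27 to 77.3 ± 7.32 (1.16, SE 0.16). A second, dim probe set of PR1b1 read -0.17 and did not pass. The genes CHS1 and CHS2 of chalcone synthase, the first enzyme of flavonoid synthesis, fell. CHS1 went from 307 ± 5.19 to 74.1 ± 10.5 (-1.85, SE 0.18) and CHS2 from 1174 ± 190 to 454 ± 12.2 (-1.33, SE 0.11). DFR, the dihydroflavonol reductase of the anthocyanin branch, fell from 287 ± 11.7 to 58.4 ± 4.07 (-2.03, SE 0.17).

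The largest fall among named genes was that of MAN1, an endo-beta-mannanase, from 200 ± 0.595 in control to 6.54 ± 5.36 in SWCNH seedlings (log2 fold change -3.29, SE 0.24). The SWCNH value lay below the level of probe sets without a target, as did those of MAN2 (-1.33, SE 0.17) and the abscission polygalacturonase TAPG4 (-1.06, SE 0.19). TSW12, a lipid transfer protein known from salt and abscisic acid treatments, fell from 2866 ± 142 to 671 ± 37.5 (-2.07, SE 0.12, adjusted p = 1.38e-06). LOC543899 fell by 1.88 (SE 0.19) and ARPI by 1.17 (SE 0.14) on the log2 scale. The xyloglucan endotransglycosylase XET2 rose from 627 ± 11.1 to 1320 ± 51.7 (SE 0.16) and pip1 from 15.3 ± 5.52 to 50.7 ± 9.90 (SE 0.18). LOC543986 (1.18), LOC778362 (1.09), LOC543511 (1.02) and Mdip1 (0.94) also rose. Another probe set of LOC778362 read 0.42 and those of LOC543511 0.76 and 0.85, none of which passed.

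**Figure D1:**
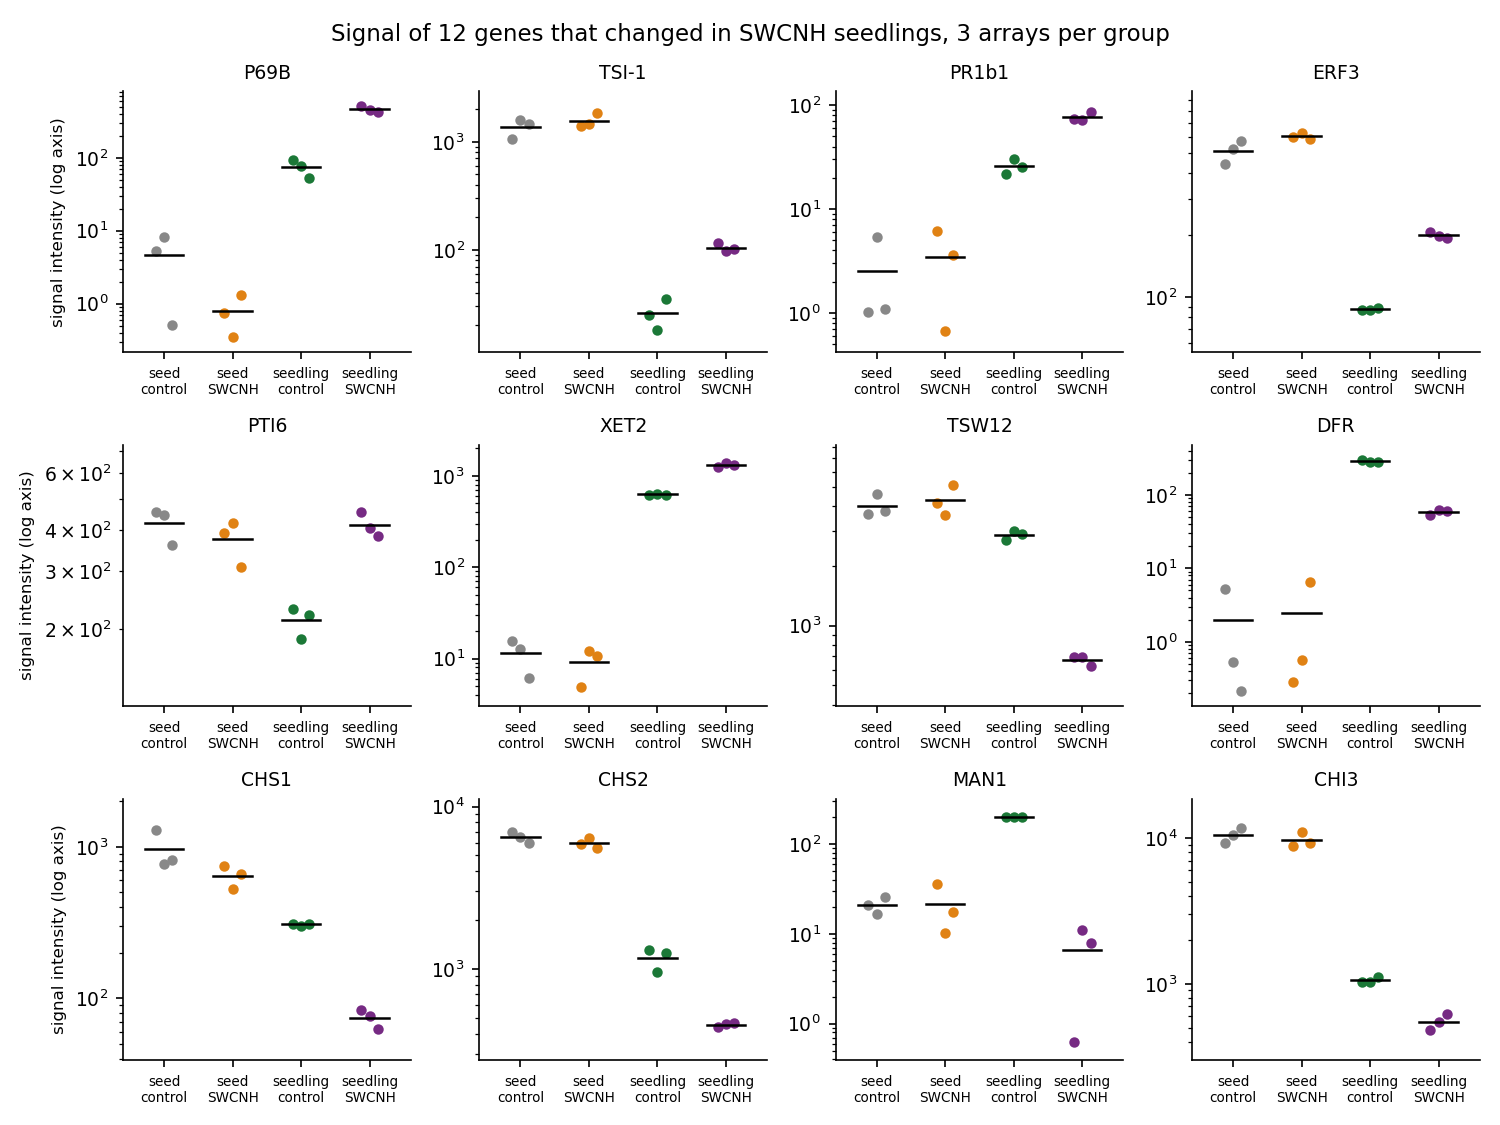
Signal intensity (log axis) of 12 genes in each of the 12 arrays, by group, with points for single arrays and bars for the mean of 3. P69B rose from a mean of 74.7 to 464 in SWCNH seedlings and DFR fell from 287 to 58.4, while in seeds no gene passed limma's test. Seed signals of P69B, PR1b1 and DFR lay below the level of probe sets without a target on both media, so their seed response could not be measured.

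By list, 4 of 16 pathogenesis-related genes rose, 2 fell and 10 did not pass, with 4 and 3 when adjusted over the list alone. The risers were P69B, TSI-1, PR1b1 and LOC543878, a PR-5 gene named after its values were seen (0.57, SE 0.12), whose sign turned with scaling to the poly-A spike-ins. Those that fell were the acidic chitinase CHI3 (-0.94, SE 0.11) and PR-P2 of the PR-4 family (-0.99, SE 0.16). Among 48 ethylene genes, 8 rose, 1 fell and 39 did not pass (10 and 2 when adjusted over the list alone). ERF3, PTI4 and PTI6, transcription factors of the ethylene response family, rose by 1.06 (SE 0.11), 0.88 (SE 0.14) and 0.92 (SE 0.14), and a second, dim probe set of ERF3 read -0.01. The other risers, named after their values were seen, were ERF4 (0.84), LOC606712 (0.74), and the ethylene synthesis genes ACS6 (0.85), ACS1A (0.72) and ACO5 (0.55), of which ACO5 changed sign with poly-A scaling. The receptor gene ETR2, likewise named afterwards, fell by 0.41 (SE 0.10). Of 9 phenylpropanoid and flavonoid genes, 3 fell (CHS1, CHS2, DFR) and 1 rose, the hydroxycinnamoyl transferase gene THT7-8 (0.83, SE 0.14), with the same counts when adjusted over the list alone.

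Of 42 cell wall genes, 3 rose and 3 fell (6 and 3 when adjusted over the list alone), with XET2 and tXET-B2 (0.93, SE 0.20) among the risers and TAPG4 and the cellulase Cel1 (-1.02, SE 0.20) among those that fell. Of 5 endosperm-weakening genes, MAN1 and MAN2 fell and 3 did not pass (1 higher and 3 lower when adjusted over the list alone). Of 7 drought and osmotic genes, the lipid transfer genes TSW12 and LE16 (-0.85, SE 0.18) fell, with 1 higher and 3 lower when adjusted over the list alone. Of 23 jasmonate and wound genes, 1 rose, opr2 (0.56, SE 0.11), which changed sign with poly-A scaling, and 2 fell (3 and 6 when adjusted over the list alone). The fallers were the lipoxygenase TomloxE (-0.90, SE 0.14) and the polyphenol oxidase LOC606710 (-0.66, SE 0.13), which was named after its values were seen and whose 3 other probe sets did not pass, 1 of them with the opposite sign. Of 10 auxin genes, IAA17 (0.81, SE 0.16) and IAA27 (0.54, SE 0.14, sign turned with poly-A scaling) rose (3 when adjusted over the list alone), and a second probe set of each did not pass.

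Single genes passed in several further lists in seedlings. The chloroplast superoxide dismutase SODCP.2 fell by 0.60 on the log2 scale (SE 0.11), the only one of 13 scavenging genes to pass (0 and 3 when adjusted over the list alone). The metallothionein MT3 rose (0.64, SE 0.14; 1 of 10 iron and metal genes, 2 when adjusted over the list alone), as did the aquaporin TIP (0.65, SE 0.12; 1 of 2, both when adjusted over the list alone). The gibberellin oxidase 3OH-2 rose (0.49, SE 0.12; 1 of 11 gibberellin and abscisic acid genes, sign turned with poly-A scaling; 1 and 1 when adjusted over the list alone). The sulfate transporter ST2 fell by 0.67 (SE 0.16; 1 of 6 nutrient transport genes) and the chaperonin CPN21 by 0.32 (SE 0.07; 1 of 9 chaperone genes), with 1 and 2 lower when adjusted over the list alone. No gene passed among the lists for photosynthesis, ribosomal proteins, cell cycle and histones, WRKY, MYB and NAC factors, LEA proteins, peroxidases, glutathione transferases, reserve mobilisation, fermentation and the proteasome. Adjusted over the list alone, the peroxidase genes CEVI-1 and TPX2 (0.53 and 0.55), the glutathione transferase GST-T4 (0.56) and the beta-amylase BMY3 (0.36) passed as higher and the dehydrin TAS14 (-0.92) as lower. By the camera set test, 0 of 17 lists passed in seedlings, the smallest adjusted p being 0.178 for endosperm weakening, while 3 had an unadjusted p under 0.05. With all probe sets as the background, chosen after seeing the data, endosperm weakening passed as lower (adjusted p = 0.0266; against the named genes, adjusted p = 0.523 with an estimated correlation), and fry, which does not compare a list with other genes, called 8 lists, 3 higher and 5 lower.

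**Figure D2:**
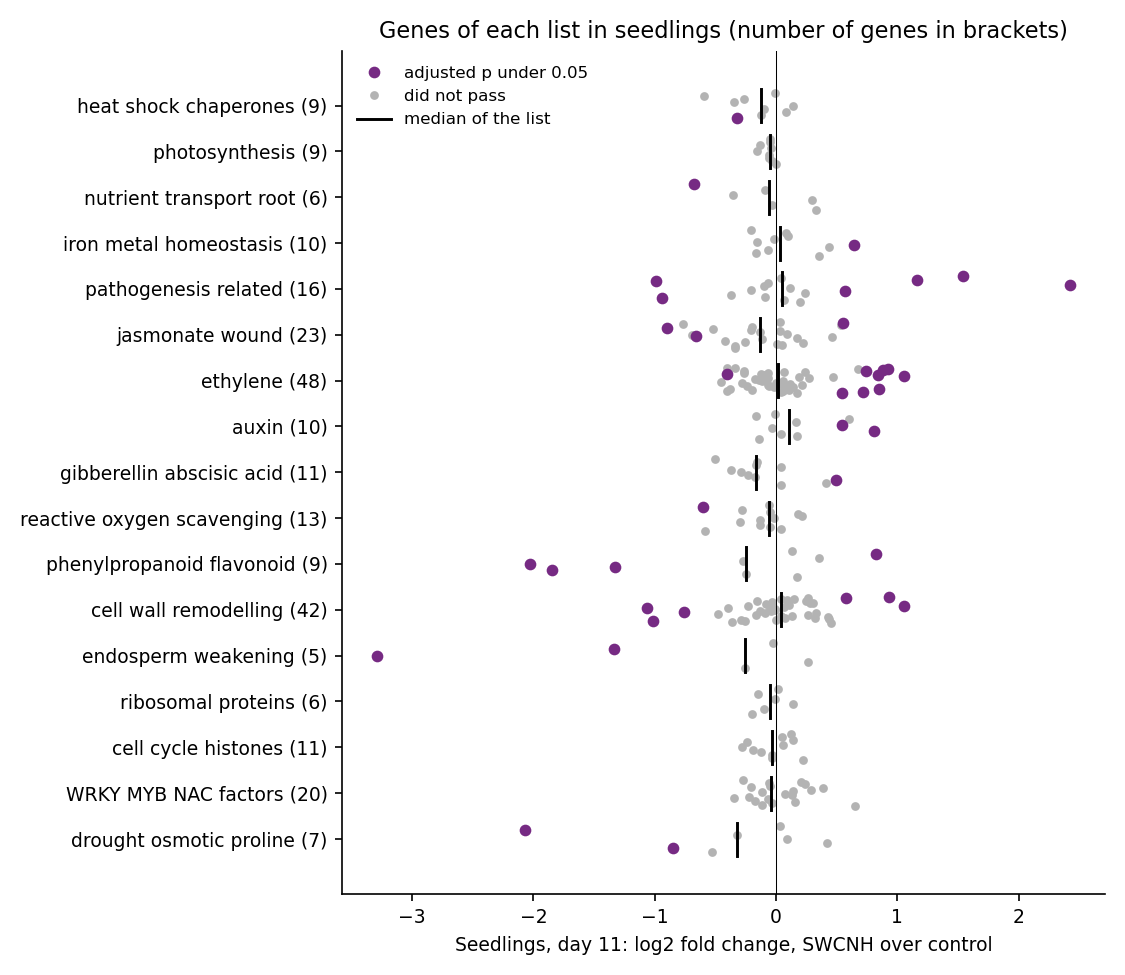
Log2 fold change of each gene, SWCNH over control seedlings, in the 17 lists with at least 5 genes on the array. Filled purple points passed limma's test, grey points did not, and black bars mark list medians, which lay between -0.32 and 0.10 on the deposited scale and were all below 0 with scaling to the poly-A spike-ins.

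In total, 377 probe sets passed limma's test in seedlings at an adjusted p under 0.05 (230 higher, 147 lower, 61.0% higher). Of these, 66 carried a gene symbol and 81 changed at least 2-fold on the transformed scale, where changes of low signals come out smaller. With scaling to the poly-A spike-ins, which were brighter by 0.61 log2 units in SWCNH seedlings (0.37 to 0.76 without 1 array), the median of all genes shifted by -0.47 and the split became 16 higher and 1155 lower. At that scaling 12 of the 66 with a gene symbol changed sign and 29 stayed past the threshold with the same sign. The number that stayed was 51 with each array centred on its median and 61 with quantile normalization. The count was 179 without control replicate 1, 171 without control replicate 2, 210 without SWCNH replicate 1, 160 without SWCNH replicate 2 and 193 without SWCNH replicate 3.

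Of 35 genes named by the rule that passed in seedlings, 22 stayed past the threshold with quantile normalization, with only the 6 seedling arrays and without each array in turn. The call of TAPG4 ended with quantile normalization (log2 fold change -0.79, adjusted p = 0.0920). The calls of ST2, MT3 and 3OH-2 ended without any 1 of the 6 seedling arrays (adjusted p from 0.0515 to 0.150). Those of CPN21 and IAA27 ended without any except control replicate 3 (0.0600 to 0.221), and that of LE16 without any except control replicate 2 (0.0552 to 0.0868). The call of LOC543511 ended without control replicate 1 or 2 or SWCNH replicate 1 or 2 (0.0507 to 0.0860). Those of tXET-B2 and IAA17 ended without control replicate 1 or 2 or SWCNH replicate 2 or 3 (0.0521 to 0.114). For Cel1 and opr2 the arrays were control replicate 1 and SWCNH replicates 2 and 3 (0.0563 to 0.0712), and for TIP control replicate 2 (0.0574).

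Whether seedlings responded differently from seeds was tested as an interaction, the SWCNH effect in seedlings minus that in seeds. P69B had the largest positive difference among named genes, 2.70 (SE 0.27, adjusted p = 2.82e-04). Its signals in seeds (0.799 on SWCNH, 4.61 on control medium) lay below the level of probe sets without a target, so its response in seeds could not be measured. PTI4, PTI6 and TSI-1 differed by 1.12 (SE 0.20), 1.09 (SE 0.20) and 1.33 (SE 0.25), and LOC544187 by 0.91 (SE 0.13). MAN1 differed by -3.25 (SE 0.34), TSW12 by -2.15 (SE 0.17), LOC543899 by -2.23 (SE 0.27), DFR by -2.06 (SE 0.24) and ARPI by -1.62 (SE 0.20). DFR and ARPI were also below the level of probe sets without a target in seeds of both media, and LOC543899 in control seeds. MAN1 and TSW12, which were above it, had seed log2 fold changes of -0.04 and 0.09. The seed signals of MAN1 were low (21.2 on control and 21.5 on SWCNH medium), so a fall of the seedling size could not have shown there. The call of PTI4 ended without seed control replicate 2, seedling control replicate 1 or 2, or any SWCNH seedling array (adjusted p from 0.0554 to 0.0686). That of PTI6 ended without seed control replicate 2, seedling control replicate 2, or SWCNH seedling replicate 1 or 2 (0.0621 to 0.0780). That of TSI-1 ended without any 1 of 8 arrays, namely seed control replicate 2, SWCNH seed replicates 1 and 2, seedling control replicates 1 and 2, and each SWCNH seedling array (0.0538 to 0.0813).

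In total, 91 probe sets passed the interaction test in limma (55 higher, 36 lower), 23 of them with a gene symbol. In seeds of both media, 16 of the 91 and 66 of the 377 called in seedlings were below the level of probe sets without a target. The count was 193 without seed control replicate 1, 39 without seed control replicate 2, 37 and 34 without seedling control replicates 1 and 2, and 46, 38 and 40 without SWCNH seedling replicates 1, 2 and 3. In simulated data 16 of 157 interaction calls were false (10.2%). Across all 10101 probe sets the log2 fold changes of seeds and seedlings correlated with Pearson's r of 0.128 and Spearman's rho of 0.150, and 56.8% had the same sign. Probe sets are not independent replicates, and 49 of 200 regroupings of the arrays within each stage gave an r as large with the same sign. Without seed control replicate 1 the correlation was 0.000843. Over the 377 probe sets called in seedlings, r was 0.0586 and 52.0% had the same sign.

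**Figure D3:**
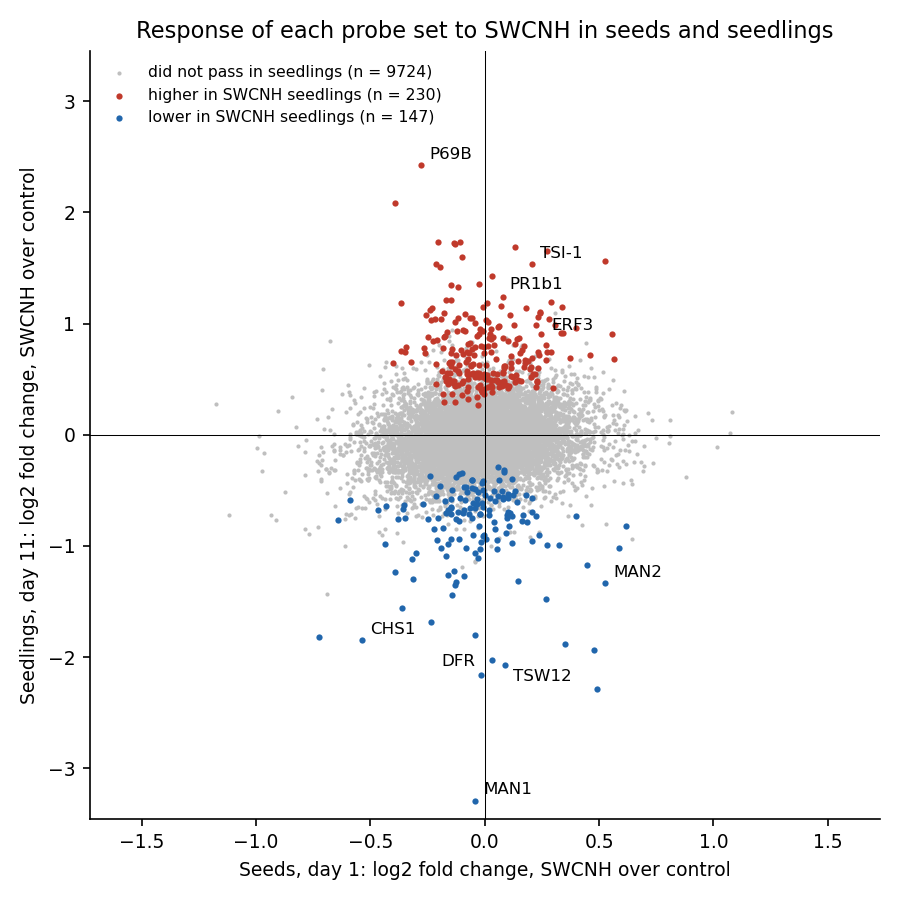
Log2 fold change on SWCNH over control medium for 10101 probe sets, seeds on the x axis and seedlings on the y axis, with the 230 higher and 147 lower in seedlings in colour. The coloured points spread widely along the seedling axis and lie close to 0 along the seed axis, with TSW12 at -2.07 in seedlings and 0.09 in seeds. They were coloured because they passed in seedlings, which by itself sets their spread along that axis. In seeds 66 of these 377 lay below the level of probe sets without a target, where the added 16 holds values near 0.

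Seedlings and seeds on control medium were compared to describe development between day 1 and day 11. Genes of photosynthesis were among those that rose most, among them PsbQ, a protein of the oxygen-evolving complex, from 10.3 ± 2.42 in seeds to 7199 ± 419 in seedlings (SD, n = 3; log2 fold change 8.10, SE 0.12, limma adjusted p = 1.2e-15). PSBO of the same complex rose by 8.17 (SE 0.12), the chlorophyll-binding protein gene CAB6A by 7.98 (SE 0.12) and plastocyanin, PETE, by 7.72 (SE 0.13). The carbonic anhydrase ca2 rose by 8.38 (SE 0.11) and the metallothionein MTA by 7.96 (SE 0.13), from a seed signal below the level of probe sets without a target. DREB1, a dehydration-response transcription factor, fell most among named genes, from 1721 ± 85.9 to 9.89 ± 8.19 (-6.12, SE 0.20), a seedling value below the level of probe sets without a target. XET4 (-5.31, SE 0.12), the kinase subunit gene SNF4 (-5.09, SE 0.14), TSI-1 (-5.04, SE 0.18), MAN2 (-4.46, SE 0.17), the arginase ARG1 (-3.78, SE 0.09) and the galactinol synthase GolS-1 (-3.30, SE 0.21) also fell.

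By list, 9 of 9 photosynthesis genes rose and 6 of 6 ribosomal protein genes fell, RPL8 by 1.21 (SE 0.07) and RPL3 by 1.12 (SE 0.09) on the log2 scale. These were the lists camera called (adjusted p = 5.72e-05 and 0.00289), and both were lost with an estimated correlation (adjusted p = 0.234 with an estimated correlation). Of 11 cell cycle and histone genes 7 rose and 1 fell, with CDKB2 at 2.95 (SE 0.14) and CycB2 at 2.91 (SE 0.14), though the list's median turned from 1.00 to -0.10 with poly-A scaling. Of 42 cell wall genes 30 rose and 7 fell, and of 10 iron and metal genes 7 rose, MT2 by 6.25 (SE 0.14) and FER by 5.53 (SE 0.18). Of 9 chaperone genes 5 fell and 2 rose, with the small heat shock protein genes ER-SHSP at -3.12 (SE 0.22) and HSP17.4 at -3.20 (SE 0.29). All 4 fermentation genes fell, among them the alcohol dehydrogenase ADH2 (-2.10, SE 0.09), as did all 3 LEA and dehydrin genes, among them TAS14 (-1.65, SE 0.27). For the endosperm-weakening list, MAN2, AGAL (-2.66, SE 0.08) and EXPA4 (-1.66, SE 0.09) fell while MAN1 rose (2.55, SE 0.24). The folds of MT2, FER and CycB2 start from seed signals below the level of probe sets without a target, and that of HSP17.4 ends at one in seedlings. Counts adjusted over the list alone were the same in every list of this comparison. Apart from MAN2, the gene examples of this paragraph were picked for this comparison after their values were seen.

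Both aquaporin genes and 5 of 6 nutrient transport genes rose between seeds and seedlings, 1 nutrient transport gene fell, and so did the only proteasome gene. Among 48 ethylene genes 16 rose and 19 fell, and among 16 pathogenesis-related genes 8 rose and 6 fell, with a list median of 0.24 that became -0.32 with median centring and -0.30 with poly-A scaling. Among 23 jasmonate and wound genes 13 rose and 4 fell, with a median of 0.38 that became -0.18 and -0.17 under the same scalings. The medians of the auxin (0.67), scavenging (0.70), flavonoid (0.70) and reserve (1.00) lists turned negative with poly-A scaling (-0.38, -0.40, -0.03 and -0.07). The fry test called 16 of 17 lists, 10 higher and 6 lower.

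In total, 6961 probe sets (68.9%) passed limma's test between seedlings and seeds, 3909 higher and 3052 lower in seedlings (56.2% higher). Of these, 703 carried a gene symbol, some of them for the same gene. The split depended on scaling. It was 2573 higher and 5159 lower with each array centred on its median (shift of the median of all probe sets -0.56). With quantile normalization it was 2673 and 4465 (shift -0.37), and with poly-A scaling 1906 and 5169 (shift -0.71). In that order, 54, 38 and 110 of the 703 probe sets with a gene symbol changed sign. The 5'/3' log2 ratio was higher in seedlings (-0.87 to -0.44) than in seeds (-3.17 to -1.51), on every array, beside each gene group above. Array numbers in the labels run in one series per stage, so array batch and stage cannot be told apart.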

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

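The tests of a larger spread between seed arrays, of a differing seed response and of the poly-A signal were written after the results they address had been seen, as was the restriction to probe sets detected in seeds. Limma's test of a difference in SWCNH response between seedlings and seeds called 23 probe sets with a gene symbol, of which the rule named 10. Above the level of probe sets without a target in seeds, LOC544187 differed by 0.91 log2 units, PTI4 by 1.12 and PTI6 by 1.09. TSI-1 differed by 1.33 and TSW12 by -2.15. MAN1 differed by -3.25, but its seed signals were low (21.2 on control and 21.5 on SWCNH medium). A fall of the seedling size could not have shown there, and its SWCNH seedling signal lay below that level, so the size of its difference is not measured. For P69B (2.70), DFR (-2.06) and ARPI (-1.62) seed signals lay below that level on both media, and for LOC543899 (-2.23) on control medium, so their values set a seedling change against background and do not measure a difference in response. PTI4, PTI6 and TSI-1 lost their calls without single arrays (adjusted p up to 0.0686, 0.0780 and 0.0813). In data that no comparison used, the poly-A spike-ins were 0.61 log2 units brighter in SWCNH than in control seedlings (1.52-fold; 0.37 to 0.76 without 1 array).

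SWCNH seedlings had 377 calls and SWCNH seeds 0. A response of the same size hidden by a larger spread between seed arrays is argued against, because the 377 probe sets had a median seed log2 fold change of 0.00784 in the seedling direction (-0.0235 to 0.0258 without 1 seed array), against 0.716 in seedlings, and over the 311 of them above the level of probe sets without a target in seeds 0.00648 (-0.0331 to 0.0280), against 0.673. With the 5'/3' covariate there were still 0 calls in seeds, so correcting for integrity differences between seed arrays revealed no response. The covariate could not restore signal lost on all seed arrays, so RNA integrity as a cause stays open. A different split of the seed arrays, which follows the 5'/3' ratio (-1.93 to -1.51 against -3.17 to -2.03), gave 32 calls. Their cause may be a structure of the seed samples or a seed spread understated by the pooled fit (67 of 255 simulated calls false). No test separated these. Regroupings do not decide whether the seed response differs, since the 8 of 100 with at least 91 interaction calls (up to 260) were all among the 11 that keep the real seedling split and its effect, and the other 89 gave at most 1, and whether seeds had a smaller or another response stays open.

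Of the pathogenesis-related and flavonoid lists, 10 genes changed in SWCNH seedlings, in both directions, and camera called neither list (adjusted p = 0.363 and 0.215). With the 5'/3' covariate, 10 of 10 called genes of these lists stayed past the threshold. The log2 ratio differed between the seedling groups by only 0.120 (SE 0.131), so the covariate could take little from a group difference. RNA integrity as their cause is therefore not decided by it. A bias with signal from unequal RNA input stays open, with a Spearman correlation of 0.104 between log2 fold change and mean signal. Seedlings ahead in development stay open too, as 56.2% of called probe sets moved in the seed-to-seedling direction (56.6% to 62.7% without 1 array). A regrouping reached 67.9%, computed over as many probe sets of smallest p, since regroupings gave no calls. Seedlings behind along the seed-to-seedling difference, as the main cause of the calls, are argued against by the same 56.2%, on the deposited scaling only. Such a delay would put most of the calls in the other direction. The share lay within the range of regroupings (lowest 32.1%, the mirror of 67.9%), so it is no sign of a lean either way. No age between day 1 and day 11 was sampled, so a delay near day 11 that departs from that difference was not tested. The share was not computed at other scalings, which turn the sign of many stage differences. A delay beside other effects of SWCNH stays open.

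The poly-A spike-ins were brighter in SWCNH seedlings, with an exact permutation p of 0.10, the smallest possible with 3 against 3 arrays. A difference in array scaling is argued against, because the hybridisation spike-ins differed by only -0.0775 log2 units (-0.198 to -0.00223 without 1 array). Fewer intact transcripts in SWCNH seedlings would lower their 5'/3' log2 ratio, but it was higher, -0.62 against -0.74 on control medium. That difference of 0.120 lies within its SE of 0.131, so a difference in RNA integrity stays open. A smaller input of plant RNA relative to the spike-ins would give such a signal and was not tested, so the direction of genes that turned with poly-A scaling is open. With that scaling 16 probe sets passed as higher in seedlings, against 230 as deposited. Of the 66 called probe sets with a gene symbol, 29 stayed past the threshold with the same sign. Whether rises that lost their call with that scaling hold is open too.

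Other splits of the arrays were tested for each count. For seeds, 10 of the 10 splits had at least as many calls as the real one (0, highest other 32), which a count of 0 fixes in advance and so tests nothing. The number was 1 for seedlings (377, highest other 0) and 1 for seedlings against seeds on control medium (6961, highest other 0). With 10 splits there are too few for a share under 0.05.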

How the results depend on the processing

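The poly-A scaling, the 5'/3' covariate, the background of all probe sets and the set without the seed arrays of lowest 5'/3' ratio were chosen after seeing the data. No named gene passed with the opposite sign with quantile normalization, the 6 arrays alone, the block or leave-one-out. At other scalings, of the called probe sets with a gene symbol, 12 of 66 in seedlings changed sign with poly-A. Between stages 54 (median centring), 38 (quantile) and 110 (poly-A) of 703 did. In seeds the count of 0 became 4 at an unadjusted p with at least 2-fold, 11 with pseudocount 1, and 1 without the 2 seed arrays of lowest 5'/3' ratio, and ranged from 0 (without seed_control replicate 1) to 1 (without seed_control replicate 3). In seedlings 377 became 645 at an adjusted p under 0.10, 81 with at least 2-fold, 88 at an unadjusted p with at least 2-fold, 229 with pseudocount 1, 599 with pseudocount 64, 820 with only the 6 arrays compared, 2636 with arrayWeights (1223 higher, 1413 lower; 46.4% higher against 61.0%), whose estimation stopped before its tolerance, and 1171 scaled to the poly-A spike-ins. Leave-one-out gave 160 (without seedling_SWCNH replicate 2) to 320 (without seedling_control replicate 3), with fewer samples. The 91 probe sets whose response differs became 212 at an adjusted p under 0.10, 169 with quantile normalization, 53 with each array centred on its median, 181 with pseudocount 64, 713 with arrayWeights and 145 with a replicate block, and 34 (without seedling_control replicate 2) to 193 (without seed_control replicate 1). The labels do not say that replicate numbers pair the samples, and not every pair deviated together (correlations 0.19, -0.01 and 0.40 in seeds and 0.17, 0.06 and 0.39 in seedlings), though 7 of 12 arrays correlated best with their own number and the seed 5'/3' ratio followed the number in both media (-1.51 and -1.60, -2.03 and -1.93, -2.89 and -3.17). With the replicate block seeds had 0 calls and seedlings 470, and ST2 ended at an adjusted p of 0.0514. Between stages 6961 became 4067 with at least 2-fold, 4069 at an unadjusted p with at least 2-fold and 4110 with probe sets under the median of mean signal left out, where fewer genes were tested, and 6531 (without seedling_control replicate 2) to 6974 (without seed_control replicate 1). The 2 list shifts in seeds became 0 with camera at an estimated correlation, 0 with fry, and 1 (auxin) with all probe sets of the genes, quantile normalization, a replicate block or all probe sets as background, 1 with the lowest 25% of probe sets left out, where the endosperm list had too few genes to be tested, and 1 (without seed_control replicate 2) to 3 (without seed_control replicate 1). The 0 in seedlings became 8 with fry and 1 with all probe sets as background, and stayed 0 without any 1 array. The 2 between stages became 0 with an estimated correlation, 16 with fry and 5 with all probe sets as background, and stayed 2 without any 1 array. The correlation of responses, 0.128, was 0.0586 over probe sets called in seedlings, and 0.000843 (without seed_control replicate 1) to 0.172 (without seedling_control replicate 3). Except where fewer samples or genes are named, the cause was not tested. Low signals limit the seedling folds of MAN1, MAN2 and TAPG4 and the seed folds of P69B, DFR, ARPI, LOC543899 and MAN1.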

Other observations

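The genes of this part and the average over stages were chosen after their values were seen. Outside the fixed lists, 26 named genes passed in SWCNH seedlings, 17 higher and 9 lower. The genes GABA-TP2 and gad2 carry GAME synonyms, a name given to steroidal glycoalkaloid genes of tomato, and are the only ones among the 803 named genes that do. GABA-TP2 fell from 2129 ± 67.6 to 1304 ± 34.5 (SD, n = 3; log2 fold change -0.70, SE 0.07, limma adjusted p = 1.0e-04) and gad2 from 5331 ± 412 to 3775 ± 90.1 (-0.49, SE 0.09, adjusted p = 0.00632). The MADS-box gene AG1 fell by 0.82 and the beta-galactosidase TBG5 by 0.71 on the log2 scale. The carotenoid dioxygenase CCD1B fell by 0.59 and the brassinosteroid oxidase CYP85A1 by 0.40, with a second probe set that did not pass. The divinyl ether synthase DES (0.66) and the MADS-box gene TAGL1 (0.54, from a control signal of 4.74, below the level of probe sets without a target) rose, as did the 14-3-3 genes TFT6 (0.40) and tft10 (0.32), which turned negative with poly-A scaling (-0.20 and -0.28).

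Averaged over both stages, 105 probe sets responded to SWCNH by limma's test, 63 higher and 42 lower, and 94 of them were also called in seedlings. Of the other 11, 4 were named: the expansin EXP2 (0.41, adjusted p = 0.00402), LOC543548 (-0.41, adjusted p = 0.0411), KD1 (0.48, adjusted p = 0.0471) and SSTLE1 (0.47, adjusted p = 0.0484). The control seed signal of KD1 and both seed signals of SSTLE1 lay below the level of probe sets without a target, and another probe set of KD1 had the opposite sign in both stages (-0.17 and -0.28). The auxin list was higher in this average by camera (adjusted p = 0.00550; adjusted p = 0.467 with an estimated correlation).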
